A study of Nicotiana benthamiana with 12 samples.

How the data were processed

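Total RNA and polysome RNA of leaves from 5-week-old plants were measured by RNA sequencing after 1 h at 23 °C or 37 °C, with 3 libraries in each of 4 groups. Samples were grouped by treatment and fraction as given in their titles. The submitters' processing notes name cutadapt, HISAT2, HTSeq 0.11.0 and DESeq, without roles or order. The genome build is not given in the sources used here, and no reference genome was used, so genes carry no coordinates.

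The deposited table has 3 kinds of values. The counts per gene are deposited under the header of raw data, per the file headers, and are whole numbers that sum to 10724854 to 14485118 per library. The signal values were counts that the authors divided by 1 size factor per library, per the file headers, and the factors differed from median-of-ratios factors of the counts by a relative 1.6e-04 at most. The log2 values are log2 ratios of the group means of these normalized values, made by the authors, per the file headers. Only the counts were used for tests. The lowest count was 1 in every library and the lowest sum over 12 libraries was 22, or 10 after subtracting 1 per library, as if 1 had been added to each count and genes with few reads left out. The tests used the counts as deposited. Of the table, 2 lines were emptied for this work and are not analysed here, and 0 columns were left without a sample.

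Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10, TMM normalization, a quasi-likelihood fit with 1 mean per group over all 12 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values use TMM library sizes, and a standard error is the log2 fold change divided by the square root of its F value. The 6 comparisons were heat against mock in total RNA and in polysome RNA, the difference of these (translation efficiency, an interaction term), polysome against total RNA in mock and in heat, and the mean heat effect over both fractions. Adjusted p-values rest on spread within all 4 groups, compared or not. Counting intervals, at 95%, and bounds cover counting error only. A fold against a group whose 3 libraries were all at the lowest count is a lower bound against 3 counts over the group. With 1 to 3 reads above it, the ratio of summed reads is given with its counting interval. This depth separates such genes from 0 poorly, while well-counted genes are limited by the spread between libraries.

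The 30 gene lists, matched on the annotation text, were fixed before the data were examined. They covered chaperone families (small heat shock proteins, HSP70, HSP90, HSP100 and Clp, DnaJ, chaperonins and co-chaperones), heat shock transcription factors, cytosolic and organellar ribosomal proteins, translation factors, photosynthetic light reactions, carbon fixation, organelle-encoded genes, proteasome and ubiquitin, antioxidant enzymes, ER protein folding, galactinol and LEA proteins, bridging factor and DREB genes, RNA silencing, pre-mRNA splicing, defence, wound and jasmonate, ethylene response factors, auxin response, cell wall, histones, clock and light, and other cell types (floral and meristem, vascular, epidermis and cuticle). They were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list moves one way and compares it with no other genes, were alternatives. A list needed 5 tested genes.

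Named genes followed a rule fixed at the same time. In each heat comparison it took the 8 largest rises and falls among genes past the threshold, with an informative annotation, a mean in the upper part of all genes tested (above the median) and no overlap between the libraries compared (for efficiency, every fit with a library left out keeps the direction). From each list reported, it took the member with the smallest adjusted p each way and the most abundant member. The comparisons of polysome with total RNA took the 4 largest each way. Which lists have named members (the 5 with the smallest camera p in each heat comparison, and HtpG) was chosen after the values were seen.

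Chosen after the data were seen were 4 added lists (HtpG and endoplasmin, nuclear-encoded photosynthesis, plastid genome type and mitochondrial genome type, adjusted apart), list tests in the comparisons of polysome with total RNA, GO terms of the deposited annotation with 15 to 300 tested genes, medians by homolog length, fits without mock total libraries 6 and 7, counts less 1, and refits of the lists with another scaling or a library left out. A fit without libraries 6 and 7 leaves mock total RNA with 1 library, which is assumed to vary like the other groups. Other alternatives were RLE size factors, no filter, a mean of at least 5 CPM, DESeq2 1.42.0, limma-voom, fits of the compared libraries alone, an absolute log2 fold change over 1, each library left out, and the title number as a block. No pair of libraries agreed within sampling noise, with chi-square per degree of freedom of 1.73 to 2.1 in heat total RNA, 9.92 to 20.8 in mock total, 18.58 to 34.89 in mock polysome and 2.57 to 12.98 in heat polysome RNA.

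The efficiency test was tested on simulated data. With 200 of 33981 genes changed, 3% of those changed by a log2 of 1 and 68% of those changed by a log2 of 2 were recovered, and 5 unchanged genes were called. Intervals of medians came from 10000 bootstrap draws of genes and leave out spread between libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.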

Results

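Leaf RNA of 5-week-old Nicotiana benthamiana, a relative of tobacco used as a laboratory plant, was sequenced from plants kept at 23 °C (mock) and from plants held at 37 °C for 1 h (heat). Each treatment gave total RNA and polysome RNA, the transcripts recovered with ribosome complexes. The 12 libraries form 4 groups of 3, which the submitters describe as biological replicates. Their titles carry the numbers 5 to 7 in mock total RNA and heat polysome RNA and 2 to 4 in heat total RNA and mock polysome RNA. Total counts per library were 10724854 to 11984551 in mock total RNA, 12601286 to 14313000 in heat total RNA, 10945519 to 14474404 in mock polysome RNA and 11766622 to 14485118 in heat polysome RNA. The 100 most abundant genes held 32.53 ± 1.27%, 27.4 ± 0.44%, 44.77 ± 2.41% and 42.33 ± 2.31% of counts in these groups (mean ± SD, n = 3). Of 40763 genes, 34325 had enough counts to be tested. Levels are CPM, counts scaled to library size, as mean ± SD of 3 libraries, and changes are log2 fold changes ± SE with adjusted p from edgeR's quasi-likelihood test. Genes are named by the identifier and homology text of the deposited annotation. Many share that text, such as 10 genes with the text of the class II small heat shock protein Niben101Scf10306g00024.1. Reads of near-identical copies could have been split, so values of single copies are uncertain.

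Heat was first compared with mock in total RNA, to ask which leaf transcripts changed in abundance within 1 h. Some chaperone families rose steeply. Of 81 genes of small heat shock proteins, which bind unfolding proteins, 50 rose, with a median log2 change of 2.76, and of 54 genes of HSP70, a chaperone driven by ATP, 49 rose, with a median of 3. In the other direction, 73 of 105 genes annotated to histones and 72 of 128 auxin response genes fell, with medians of -1.46 and -1.01 (adjusted p = 0.48 and 0.17 with an estimated correlation). Among the 8 largest rises was a class II small heat shock protein (Niben101Scf10306g00024.1), from 0.0832 ± 0.0379 to 724 ± 17.5 CPM.

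At an adjusted p threshold of 0.05, 8832 genes rose and 9728 fell. Which direction held more genes depended on the processing, with 9551 up and 8846 down with RLE size factors, 9392 and 8509 with DESeq2, 9851 and 9743 without a filter and 6497 and 6262 without mock total libraries 6 and 7. In most of the 8 largest rises, mock total RNA held few or no reads above the lowest count in the files, so ratios of heat to mock are given with counting intervals. The class II small heat shock proteins Niben101Scf10306g00024.1, Niben101Scf04040g09011.1 and Niben101Scf04040g08015.1 had ratios of 35100, 32600 and 7030 (95% counting intervals 6300 to 1390000, 5860 to 1290000 and 1950 to 58100). The class IV genes Niben101Scf07321g00007.1 and Niben101Scf00705g04009.1 reached 388 ± 5.80 and 383 ± 14.4 CPM, with ratios of 18800 and 18500 (95% counting intervals 3370 to 741000 and 3330 to 732000). A class I gene (Niben101Scf01475g00019.1) rose by 11.64 ± 0.28 (adjusted p = 4.5e-14). The HSP70 genes Niben101Scf09928g01021.1 and Niben101Scf02124g01003.1 had no read above that lowest count in mock total RNA. They were at least 5310-fold higher and at least 4930-fold higher after heat (adjusted p = 4.5e-14 and 2.6e-14).

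Among the 8 largest falls, a GDSL esterase/lipase (Niben101Scf08777g02002.1), of a family of lipid hydrolases, went from 21.2 ± 4.30 to 0.204 ± 0.155 CPM and fell by 6.65 ± 0.35 (adjusted p = 2.4e-10). The GASA/Snakin genes Niben101Scf04495g00028.1 and Niben101Scf01578g00012.1, which encode small cysteine-rich peptides, fell, with log2 changes of -6.25 ± 0.66 and -5.97 ± 0.47 (adjusted p = 9.8e-07 and 3.2e-08). The other 5 were copies of plastid genes. The Rubisco large chain is the carbon-fixing subunit, and its copies Niben101Scf07103g01021.1, Niben101Scf25930g00016.1, Niben101Scf00173g09004.1 and Niben101Scf11178g01008.1 fell, with log2 changes of -6.35 ± 0.98, -6.26 ± 0.92, -5.88 ± 0.85 and -5.78 ± 0.85 (adjusted p = 5.5e-05, 3.1e-05, 2.7e-05 and 3.1e-05). A plastid ATP synthase beta subunit (Niben101Scf03068g00011.1) fell by 5.82 ± 0.81 (adjusted p = 1.9e-05). Mock total libraries 6 and 7 stood apart in such transcripts. Genes of plastid genome type summed to 571.6, 9947 and 9872 CPM in mock total libraries 5, 6 and 7, against 248.9 to 286.7 in heat total RNA. Without libraries 6 and 7, the Rubisco copies had changes of -2.59, -2.13, -1.87 and -1.85, and the ATP synthase gene of -2.5.

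Gene lists fixed before the data were examined were tested with camera. Of 81 small heat shock protein genes, 50 rose and 8 fell (50 and 8 adjusted over the list alone). The small heat shock protein list had adjusted p = 5.9e-15, and adjusted p = 0.0095 with an estimated correlation. A plastid small heat shock protein annotated as heat shock protein 21 (Niben101Scf08206g01019.1) was at least 2440-fold higher. The most abundant class I gene (Niben101Scf10384g00014.1) went from 2.05 ± 0.737 to 2975 ± 134 CPM, while a class V gene (Niben101Scf03104g03020.1) fell by 1.56 ± 0.15 (adjusted p = 2.9e-07). Of 54 HSP70 genes, 49 rose and 3 fell (49 and 3 adjusted over the list alone). The HSP70 list had adjusted p = 2.6e-23, and adjusted p = 0.00049 with an estimated correlation. The most abundant HSP70 gene (Niben101Scf12154g01009.1) rose by 4.42 ± 0.17 (adjusted p = 5e-12), while Niben101Scf04126g01011.1 fell by 1.2 ± 0.22 (adjusted p = 3e-04). Of 42 ER protein folding genes, 30 rose and 2 fell (30 and 2 adjusted over the list alone). The ER folding list had adjusted p = 2.9e-10, and adjusted p = 0.068 with an estimated correlation. The lectin chaperones calnexin (Niben101Scf01596g12004.1) and calreticulin-3 (Niben101Scf04375g04006.1) rose by 4.55 ± 0.16 and 3.95 ± 0.18 (adjusted p = 1.9e-12 and 4.7e-11). An endoplasmin homolog (Niben101Scf00752g01003.1), an HSP90 of the endoplasmic reticulum, fell by 1.95 ± 0.47 (adjusted p = 0.0025). Of 71 HSP100 and Clp genes, disaggregases and proteases, 28 rose and 8 fell (28 and 8 adjusted over the list alone). The HSP100 and Clp list had adjusted p = 0.0021, and adjusted p = 0.27 with an estimated correlation. Of 218 DnaJ genes, partners of HSP70, 87 rose and 44 fell (87 and 47 adjusted over the list alone). The DnaJ list had adjusted p = 0.0085, and adjusted p = 0.11 with an estimated correlation. Of 41 heat shock transcription factor genes, 20 rose and 5 fell (21 and 5 adjusted over the list alone). The heat shock factor list had adjusted p = 0.00069, and adjusted p = 0.1 with an estimated correlation. Of 211 chaperonin and co-chaperone genes, 75 rose and 49 fell (77 and 50 adjusted over the list alone). The chaperonin list had adjusted p = 0.0021, and adjusted p = 0.11 with an estimated correlation.

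The planned HSP90 list matched only 9 tested genes. Genes that the annotation calls HtpG, the bacterial name of HSP90, or endoplasmin formed a list added later, in which 20 of 23 rose and 1 (Niben101Scf00752g01003.1) fell. The HtpG list had adjusted p = 1.9e-14, and adjusted p = 0.00092 with an estimated correlation. Its most abundant member (Niben101Scf04847g03018.1) went from 8.54 ± 1.33 to 1437 ± 32.3 CPM, and Niben101Scf03114g03011.1 had a ratio of 6500 (95% counting interval 1800 to 53700) of heat to mock.

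Of 184 pre-mRNA splicing genes, 80 rose and 24 fell (80 and 24 adjusted over the list alone). The splicing list had adjusted p = 0.00044, and adjusted p = 0.1 with an estimated correlation. Of 346 translation factor genes, 120 rose and 52 fell adjusted over the list alone, and 53 fell adjusted over all genes. The translation factor list had adjusted p = 0.01, and adjusted p = 0.1 with an estimated correlation. Of 128 auxin response genes, 16 rose and 72 fell (18 and 77 adjusted over the list alone). The auxin list had adjusted p = 3.2e-06, and adjusted p = 0.17 with an estimated correlation. An auxin-induced protein 12 gene (Niben101Scf00228g02006.1) fell by 4.29 ± 0.21 (adjusted p = 9.7e-11) and the auxin-inducible regulator IAA9 (Niben101Scf03068g03009.1) fell by 1.24 ± 0.15 (adjusted p = 3.4e-06). A SAUR-like gene (Niben101Scf09387g04001.1) rose by 3.85 ± 0.24 (adjusted p = 1.6e-09). Of 105 genes annotated to histones, 4 rose and 73 fell (5 and 77 adjusted over the list alone). The histone list had adjusted p = 8.8e-09, and adjusted p = 0.48 with an estimated correlation. A histone H1 gene (Niben101Scf04361g01001.1) fell by 3.51 ± 0.17 (adjusted p = 1.2e-10) and an H2A.1 gene (Niben101Scf03277g02012.1) rose by 0.86 ± 0.15 (adjusted p = 0.00021). The most abundant H2B gene (Niben101Scf02182g02007.1) had a log2 change of -0.46 ± 0.24 that did not pass (adjusted p = 0.11). Of 58 floral and meristem regulators, a list for other cell types, 8 rose and 32 fell (8 and 33 adjusted over the list alone). The floral and meristem list had adjusted p = 0.0035, and adjusted p = 0.11 with an estimated correlation. Of 73 clock and light genes, 9 rose and 30 fell (10 and 30 adjusted over the list alone). The clock and light list had adjusted p = 0.015, and adjusted p = 0.45 with an estimated correlation, and the call ended without mock total library 5 (adjusted p = 0.052).

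Photosynthesis and ribosome lists also fell in total RNA, together with the plastid transcripts that stood apart in mock libraries 6 and 7. Of 250 light reaction genes, 16 rose and 126 fell (16 and 128 adjusted over the list alone). The light reaction list had adjusted p = 6.6e-05, and adjusted p = 0.5 with an estimated correlation. Its median moved from -0.57 to -0.38 without libraries 6 and 7. Of 76 carbon fixation genes, 5 rose and 39 fell (5 and 39 adjusted over the list alone). The carbon fixation list had adjusted p = 0.00069, and adjusted p = 0.45 with an estimated correlation. The carbon fixation median moved from -0.62 to -0.66 without them. Of 388 cytosolic ribosomal protein genes, 20 rose and 139 fell (19 and 121 adjusted over the list alone). The cytosolic ribosomal list had adjusted p = 0.00078, and adjusted p = 0.73 with an estimated correlation. That call ended without library 7 (adjusted p = 0.076) and without both libraries (14 and 19, adjusted p = 0.14). Of 396 organellar ribosomal protein genes, 17 rose and 166 fell (17 and 163 adjusted over the list alone). The organellar ribosomal list had adjusted p = 8.9e-05, and adjusted p = 0.5 with an estimated correlation. Without both, 16 and 64 of these passed (adjusted p = 0.052). Of 67 organelle-encoded genes, 1 rose and 55 fell (1 and 55 adjusted over the list alone). The organelle-encoded list had adjusted p = 4.7e-06, and adjusted p = 0.53 with an estimated correlation. Its median moved from -3.76 to -0.48 without both. In a list added later, 100 of 105 genes of plastid genome type fell (adjusted p = 1.3e-12, and adjusted p = 0.62 with an estimated correlation). Without both libraries their median moved from -4.1 to -0.78, still downward. Of 50 genes of mitochondrial genome type, 6 rose and 21 fell (adjusted p = 0.77). Their median was -1.26, and 1.77 without both. Nuclear-encoded photosynthesis genes had 10 rises and 34 falls among 138 (adjusted p = 0.11). Their median was -0.13, and -0.16 without both.

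The other 12 planned lists were not called in total RNA, with adjusted p of 0.056 to 0.86. The numbers that rose and fell, with those adjusted over the list alone in parentheses, were 3 and 1 of 9 (3 and 1) for HSP90 chaperones, 21 and 12 of 115 (16 and 5) for proteasome and ubiquitin, 71 and 83 of 279 (71 and 84) for antioxidant enzymes and 14 and 14 of 51 (14 and 14) for galactinol and LEA proteins. They were 1 and 2 of 8 (1 and 1) for multiprotein bridging factor and DREB, 15 and 7 of 40 (15 and 7) for RNA silencing, 60 and 59 of 206 (60 and 60) for defence genes and 9 and 32 of 62 (11 and 32) for wound and jasmonate genes. For the rest they were 58 and 47 of 150 (59 and 49) for ethylene response factors, 62 and 105 of 253 (62 and 109) for cell wall genes, 8 and 9 of 33 (8 and 9) for vascular tissue and 29 and 43 of 130 (29 and 43) for epidermis and cuticle. The wound and jasmonate list was called without mock total library 7 or mock polysome library 4 (adjusted p = 0.029 and 0.035), with RLE size factors (adjusted p = 0.048), by fry (adjusted p = 0.00067) and without mock total libraries 6 and 7 together (adjusted p = 0.038). The bridging factor and DREB list had a median of -0.17 and a mean of 0.68, and its test pointed down. Median and mean also differed in sign for proteasome and ubiquitin (-0.01 and 0.04), antioxidant enzymes (-0.04 and 0.03), galactinol and LEA proteins (0.02 and -0.05) and vascular tissue (0.2 and -0.1).

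**Figure D1:**
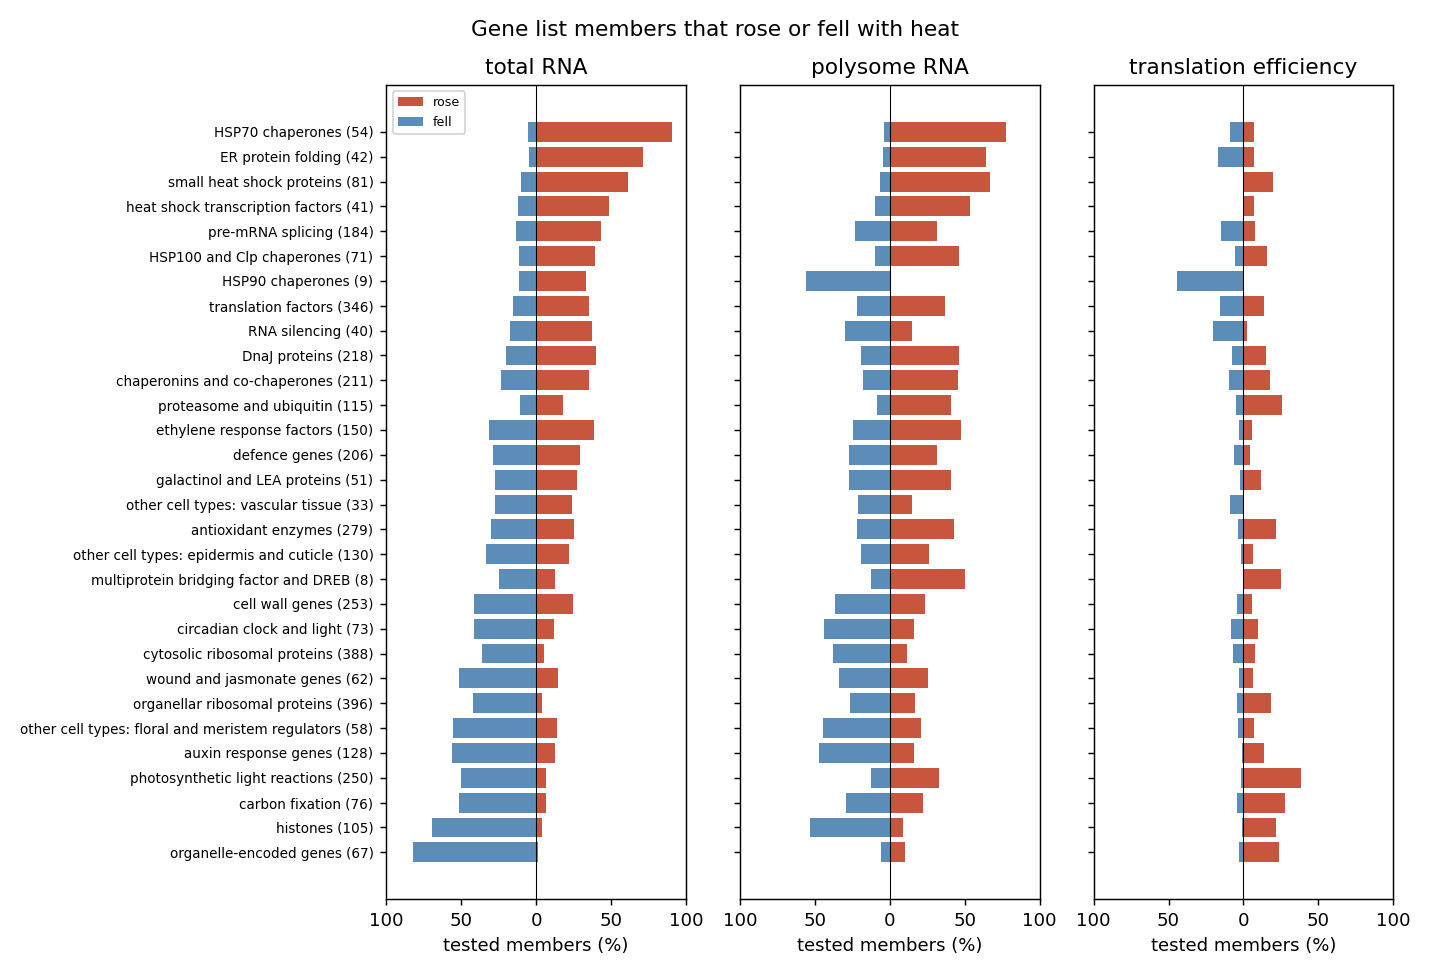
Share of the tested members of each of the 30 planned gene lists (number tested in parentheses) that rose (red, to the right) or fell (blue, to the left) with heat, in percent, in total RNA, polysome RNA and translation efficiency. HSP70 chaperones, at the top, rose in 49 of 54 genes in total RNA and 42 in polysome RNA, and photosynthetic light reactions fell in 126 of 250 in total RNA and rose in 96 in efficiency (45 and 39 without mock total libraries 6 and 7).

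**Figure D2:**
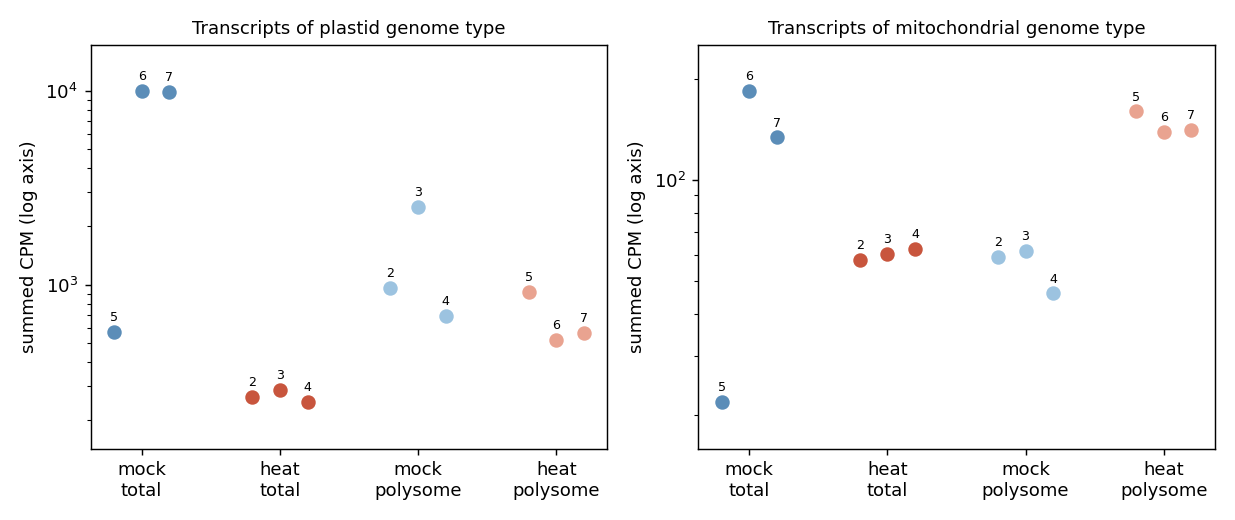
Summed CPM (log axis) of transcripts of plastid genome type (left) and mitochondrial genome type (right), 1 point per library, labelled with its number, in the 4 groups. Mock total libraries 6 and 7 lie at 9947 and 9872 CPM for the plastid type and library 5 at 571.6.

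In polysome RNA, the comparison asked which transcripts changed among those carried by ribosomes. Small heat shock proteins and HSP70 rose here too, in 54 of 81 and 42 of 54 genes, with median log2 changes of 3.99 and 2.76. The most abundant class I small heat shock protein (Niben101Scf10384g00014.1) went from 3.93 ± 1.61 to 14540 ± 3380 CPM. Histone, auxin response and clock genes fell as lists (adjusted p = 0.44 to 0.77 with an estimated correlation). Among the 8 largest falls named by the fixed rule was TCP4 (Niben101Scf08142g03005.1), a regulator of leaf growth, from 55.0 ± 3.19 to 0.741 ± 0.00499 CPM.

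At the same threshold 9632 genes rose and 9605 fell. More fell than rose with 1 subtracted from the counts (9580 and 9566), a mean of at least 5 CPM (6261 and 5985) or a log2 change over 1 (6934 and 6437). The 8 largest rises were all small heat shock proteins. Of class II, Niben101Scf04040g09011.1 and Niben101Scf04040g08015.1 had ratios of 78200 and 27900 (95% counting intervals 14000 to 3090000 and 5020 to 1100000) of heat to mock, and Niben101Scf04040g09016.1 and Niben101Scf10306g00024.1 rose by 12.83 ± 0.4 and 12.32 ± 0.3 (adjusted p = 5.5e-13 and 3.7e-14). The class IV genes Niben101Scf00705g04009.1 and Niben101Scf07321g00007.1 rose by 13.16 ± 0.25 and 13.06 ± 0.3 (adjusted p = 1.2e-14 and 2e-14). The class I genes Niben101Scf01475g00019.1 and Niben101Scf10384g00015.1 rose by 13.14 ± 0.29 and 12.59 ± 0.46 (adjusted p = 1.9e-14 and 3.2e-12). Among the 8 largest falls, TCP4 fell by 6.2 ± 0.23 (adjusted p = 3.2e-12). The GDSL esterase/lipase Niben101Scf08777g02002.1 and the GASA/Snakin gene Niben101Scf01578g00012.1 fell, with log2 changes of -6.1 ± 0.38 and -6.01 ± 0.48 (adjusted p = 1.8e-09 and 3.5e-08). A cytosolic sulfotransferase 17 (Niben101Scf01143g02025.1) fell by 6.01 ± 0.5 (adjusted p = 5.6e-08), and an inhibitor of fructosidase (Niben101Scf00618g05002.1), which restrains sucrose-cleaving enzymes, fell by 5.81 ± 0.61 (adjusted p = 8.8e-07). The cell cycle gene cyclin-D6-1 (Niben101Scf04122g01009.1) went from 13.5 ± 4.35 CPM to 1 to 3 reads above the minimum, a ratio of 335 (95% counting interval 59.8 to 13300) of mock to heat (adjusted p = 4e-08). The cytochrome P450 genes Niben101Scf18418g02007.1 and Niben101Scf01133g11002.1 had ratios of 154 and 203 (95% counting intervals 52.3 to 747 and 55.9 to 1680) of mock to heat (adjusted p = 5.1e-10 and 0.00026).

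Of 81 small heat shock protein genes, 54 rose and 5 fell (55 and 8 adjusted over the list alone). The small heat shock protein list had adjusted p = 1.7e-17, and adjusted p = 0.0053 with an estimated correlation. The class V gene Niben101Scf03104g03020.1 fell by 1.79 ± 0.15 (adjusted p = 5.2e-08). Of 54 HSP70 genes, 42 rose and 2 fell (42 and 2 adjusted over the list alone). The HSP70 list had adjusted p = 5.2e-17, and adjusted p = 0.0017 with an estimated correlation. The HSP70 gene Niben101Scf02124g01003.1 had a ratio of 10100 (95% counting interval 1820 to 400000) of heat to mock. Niben101Scf12154g01009.1 rose by 4.93 ± 0.17 (adjusted p = 1.8e-12) and Niben101Scf04126g01011.1 fell by 2.47 ± 0.26 (adjusted p = 9.5e-07). Of 71 HSP100 and Clp genes, 33 rose and 7 fell (33 and 7 adjusted over the list alone). The HSP100 and Clp list had adjusted p = 0.00044, and adjusted p = 0.21 with an estimated correlation. Genes annotated ClpB, a disaggregase, were on both sides, since Niben101Scf15972g01024.1 rose by 9.12 ± 0.25 (adjusted p = 1.6e-13) and Niben101Scf02034g02001.1 fell by 3.06 ± 0.27 (adjusted p = 1.2e-07). The most abundant member, a proteolytic Clp subunit rather than a chaperone (Niben101Scf01700g01004.1), rose by 0.74 ± 0.18 (adjusted p = 0.0023). Of 41 heat shock transcription factor genes, 22 rose and 4 fell (22 and 4 adjusted over the list alone). The heat shock factor list had adjusted p = 0.00032, and adjusted p = 0.083 with an estimated correlation. Heat shock factors A-6b (Niben101Scf03923g03003.1) and A2 (Niben101Scf01777g02001.1) rose by 6.69 ± 0.19 and 6.11 ± 0.24 (adjusted p = 2.5e-13 and 5.7e-12), while B-4b (Niben101Scf08191g00001.1) fell by 1.9 ± 0.31 (adjusted p = 7.7e-05). Of 42 ER protein folding genes, 27 rose and 2 fell (27 and 3 adjusted over the list alone). The ER folding list had adjusted p = 5.9e-06, and adjusted p = 0.11 with an estimated correlation. Calnexin Niben101Scf01596g12004.1 and calreticulin-3 Niben101Scf04375g04006.1 rose by 4.43 ± 0.16 and 4.77 ± 0.19 (adjusted p = 3.1e-12 and 8.1e-12). Endoplasmin Niben101Scf00752g01003.1 fell, with a ratio of 11 (95% counting interval 2.78 to 95.6) of mock to heat (adjusted p = 0.0027). In the added HtpG list, 18 of 23 rose and 1 (Niben101Scf00752g01003.1) fell (adjusted p = 5.6e-11, and adjusted p = 0.0025 with an estimated correlation). Its members Niben101Scf04847g03018.1 and Niben101Scf03114g03011.1 reached 1918 ± 106 and 153 ± 9.49 CPM.

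Of 218 DnaJ genes, 102 rose and 43 fell adjusted over the list alone, and 42 fell adjusted over all genes. The DnaJ list had adjusted p = 0.0028, and adjusted p = 0.087 with an estimated correlation. Of 211 chaperonin and co-chaperone genes, 96 rose and 37 fell (97 and 37 adjusted over the list alone). The chaperonin list had adjusted p = 7e-04, and adjusted p = 0.11 with an estimated correlation. Of 279 antioxidant enzyme genes, 119 rose and 60 fell (120 and 60 adjusted over the list alone). The antioxidant list had adjusted p = 0.013, and adjusted p = 0.44 with an estimated correlation. Of 115 proteasome and ubiquitin genes, 47 rose and 10 fell (45 and 9 adjusted over the list alone). The proteasome list had adjusted p = 0.0061, and adjusted p = 0.44 with an estimated correlation. Of 150 ethylene response factor genes, 71 rose and 37 fell (73 and 38 adjusted over the list alone). The ethylene factor list had adjusted p = 0.016, and adjusted p = 0.11 with an estimated correlation. Of 128 auxin response genes, 21 rose and 60 fell (22 and 60 adjusted over the list alone). The auxin list had adjusted p = 0.0061, and adjusted p = 0.44 with an estimated correlation. Of 73 clock and light genes, 12 rose and 32 fell (12 and 32 adjusted over the list alone). The clock and light list had adjusted p = 0.012, and adjusted p = 0.44 with an estimated correlation. Of 105 genes annotated to histones, 9 rose and 56 fell (9 and 56 adjusted over the list alone). The histone list had adjusted p = 0.0021, and adjusted p = 0.77 with an estimated correlation. Of 388 cytosolic ribosomal protein genes, 44 rose and 148 fell (42 and 139 adjusted over the list alone). The cytosolic ribosomal list had adjusted p = 0.0088, and adjusted p = 0.84 with an estimated correlation. The histone and cytosolic ribosomal calls ended without mock polysome library 2 (adjusted p = 0.079 and 0.14). The other 16 planned lists had adjusted p of 0.11 to 0.72. Among them, 5 of 9 genes of the planned HSP90 list fell (5 adjusted over the list alone), against the direction of the HtpG list (median -0.69, adjusted p = 0.22, and by fry adjusted p = 0.0015). Of the rest, 82 of 250 light reaction genes rose and 32 fell (79 and 30 adjusted over the list alone), against 83 and 68 in the fit without mock total libraries 6 and 7. Their median of -0.02 and mean of -0.1 lay below 0 while the test pointed up. Epidermis and cuticle genes had a median of -0.05 and a mean of 0.12.

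**Figure D3:**
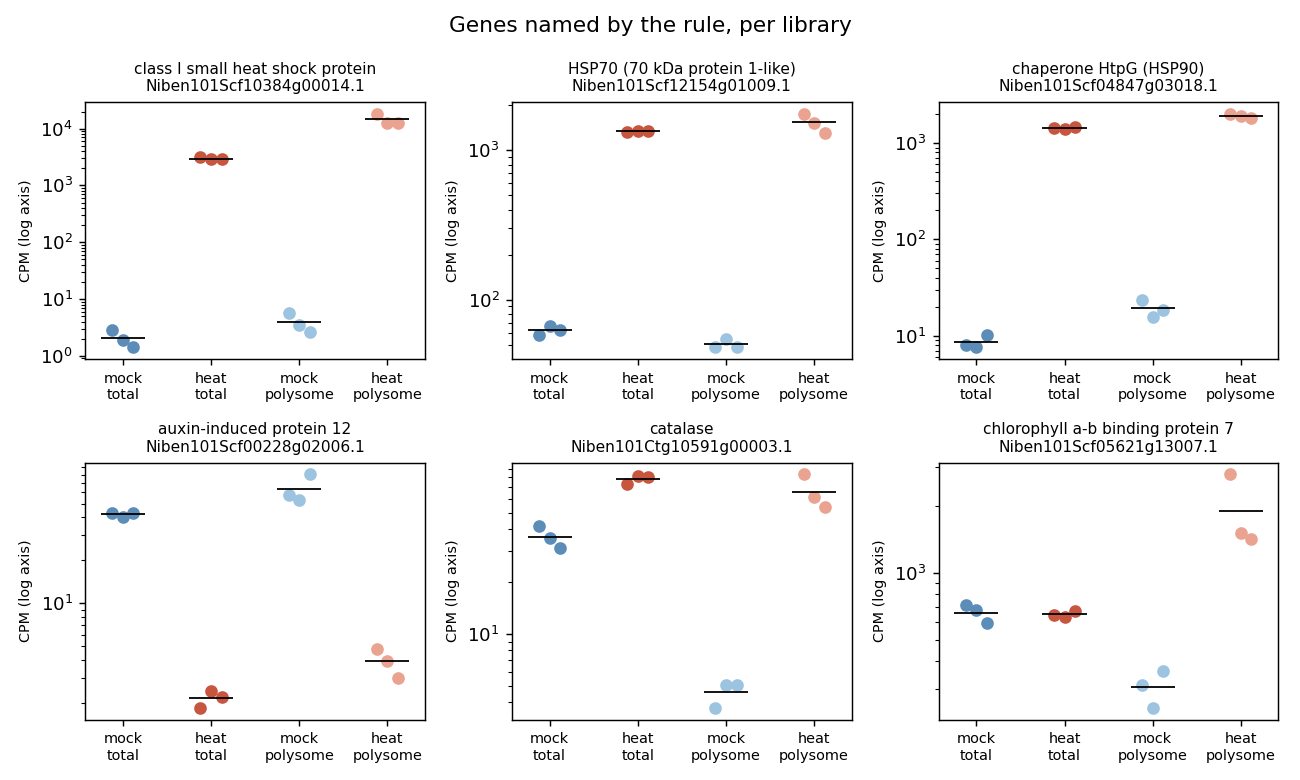
CPM (log axis) of 6 genes named by the fixed rule, 1 point per library and a line at the mean of each group of 3. The class I small heat shock protein Niben101Scf10384g00014.1 goes from 2.05 ± 0.737 to 2975 ± 134 CPM in total RNA and from 3.93 ± 1.61 to 14540 ± 3380 in polysome RNA.

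Across the 34325 genes, the changes in polysome RNA and total RNA had a Pearson correlation of 0.819 and a Spearman correlation of 0.736, with a total least squares slope of 1.077. These comparisons share no library, and genes are not independent replicates. The mean of the total RNA and polysome RNA effects called 10744 genes up and 11815 down (11078 and 10948 with DESeq2).

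**Figure D4:**
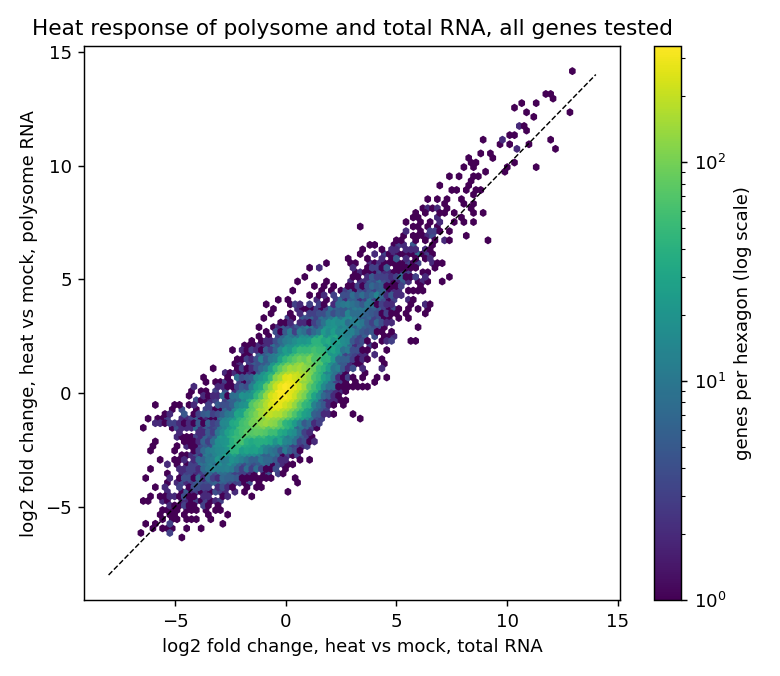
Log2 fold change with heat in polysome RNA (vertical) against total RNA (horizontal) for the 34325 genes tested, coloured by the number of genes per hexagon on a log scale, with a dashed line where both are equal. Genes at the upper right include the class I small heat shock protein Niben101Scf01475g00019.1, at 11.64 in total RNA and 13.14 in polysome RNA.

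The comparison named in the series title asks how heat changed translation efficiency, taken as polysome RNA relative to total RNA in heat against the same ratio in mock plants. It is relative, and gives no absolute rate of translation. Light reaction genes rose in 96 of 250 and small heat shock proteins in 16 of 81 genes, while RNA silencing and HSP90 genes fell in 8 of 40 and 4 of 9 (adjusted p = 0.081 to 0.35 with an estimated correlation). Without mock total libraries 6 and 7, which stood apart, the same counts were 39, 7, 4 and 2. A chlorophyll a-b binding protein 7 (Niben101Scf05621g13007.1), part of the light-harvesting antenna, had 663 ± 61.7 and 653 ± 21.8 CPM in mock and heat total RNA, while its polysome RNA went from 307 ± 58.5 to 1903 ± 760 CPM. A catalase (Niben101Ctg10591g00003.1), which breaks down hydrogen peroxide, rose by 2.73 ± 0.26 (adjusted p = 5.7e-05) in efficiency.

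In a single model of all libraries with an interaction term, 3502 genes rose and 2891 fell in efficiency. The larger direction turned with RLE size factors (3085 up and 3246 down) and with DESeq2 (3313 and 3388). Of the 8 largest rises, GTPase Der (Niben101Scf39490g00008.1), a ribosome assembly factor in bacteria, rose by 4.42 ± 0.35 (adjusted p = 2.2e-05). Its polysome RNA went from 0.309 ± 0.0254 to 9.58 ± 2.33 CPM. The other 7 were plastid genes. The Rubisco large chain copies Niben101Scf25930g00016.1, Niben101Scf07103g01021.1, Niben101Scf11178g01008.1 and Niben101Scf00173g09004.1 rose by 5.03 ± 1.17, 4.81 ± 1.4, 4.64 ± 1.03 and 4.56 ± 1.03 (adjusted p = 0.0086, 0.026, 0.0067 and 0.0072). The ATP synthase beta subunit Niben101Scf03068g00011.1 rose by 4.52 ± 1.21 (adjusted p = 0.018), and the cytochrome b559 genes Niben101Scf02160g06002.1 and Niben101Scf03236g02005.1 rose by 4.5 ± 1.1 and 4.37 ± 1 (adjusted p = 0.011 and 0.0078). Without mock total libraries 6 and 7 these 7 had log2 changes of 0.57 to 1.23. With 1 library left out, Niben101Scf07103g01021.1 lost its call (3.99 to 4.92, adjusted p = 0.054 to 0.16, without heat total 2, 3 or 4, mock polysome 4 or heat polysome 5). So did Niben101Scf03068g00011.1 (3.93, adjusted p = 0.11, without heat polysome 5).

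Among the 8 largest falls, a receptor-like protein kinase 5 (Niben101Scf07488g00024.1) fell by 3.45 ± 0.89 (adjusted p = 0.015) and had -3.55 without mock total libraries 6 and 7, a change as large that did not pass (adjusted p = 0.06). An ATP-dependent RNA helicase A (Niben101Scf03550g00021.1) fell by 3.22 ± 0.37 (adjusted p = 0.00018). A phosphoadenosine phosphosulfate reductase (Niben101Scf00327g00011.1) of sulfate assimilation fell by 3.22 ± 0.34 (adjusted p = 0.00012), and a gene annotated as dynein light chain 1 (Niben101Scf01395g05008.1) fell by 3.2 ± 0.36 (adjusted p = 0.00015). Auxin response factor 5 (Niben101Scf01869g00012.1), a regulator of auxin-responsive genes, fell by 3.06 ± 0.4 (adjusted p = 0.00033). A nucleolar U3snoRNP10 domain protein (Niben101Scf03809g00009.1) and an acetyl-coenzyme A synthetase (Niben101Scf02072g02027.1) fell, with log2 changes of -3.01 ± 0.36 and -2.96 ± 0.4 (adjusted p = 0.00023 and 4e-04). An RNA polymerase subunit RPABC2 gene (Niben101Scf03861g02041.1) fell by 2.96 ± 0.5 (adjusted p = 0.0014). Its total RNA went from 0.394 ± 0.0466 to 23.9 ± 1.68 CPM and its polysome RNA from 0.558 ± 0.392 to 4.09 ± 0.354.

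Of 81 small heat shock protein genes, 16 rose and 0 fell (20 and 0 adjusted over the list alone). The small heat shock protein list had adjusted p = 1.9e-09, and adjusted p = 0.081 with an estimated correlation. At an unadjusted p under 0.05, 2 fell in edgeR, and DESeq2 called 18 up and 0 down. The class I gene Niben101Scf09262g01017.1 rose by 1.51 ± 0.24 (adjusted p = 0.0011). Niben101Scf10384g00014.1 rose by 1.34 ± 0.4 (adjusted p = 0.028) and lost its call with 1 library left out (1.02 to 1.36, adjusted p = 0.057 to 0.1, without mock total 5, heat total 2, 3 or 4, mock polysome 3 or 4 or heat polysome 5). Niben101Scf06869g00010.1 had -2.21 ± 0.84 (adjusted p = 0.079). Genes outside the list with homologs of 100 to 250 residues, a range that holds small heat shock proteins, had a median of 0.37. Of 250 light reaction genes, 96 rose and 4 fell (126 and 9 adjusted over the list alone). The light reaction list had adjusted p = 6.4e-12, and adjusted p = 0.35 with an estimated correlation. Without mock total libraries 6 and 7 its median moved from 0.94 to 0.41. The antenna gene Niben101Scf05621g13007.1 rose by 2.66 ± 0.32 (adjusted p = 0.00023). A photosystem II X protein (Niben101Scf04018g06007.1) fell by 0.86 ± 0.24 (adjusted p = 0.019), and had -0.82, adjusted p = 0.051 to 0.058, without heat total 2 or heat polysome 6. It had -0.67 (adjusted p = 0.19) without mock total libraries 6 and 7. The most abundant member, a photosystem II 10 kDa polypeptide (Niben101Scf01116g01004.1), had -0.12 ± 0.27 (adjusted p = 0.8).

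Of 279 antioxidant enzyme genes, 61 rose and 10 fell (68 and 12 adjusted over the list alone). The antioxidant list had adjusted p = 0.00053, and adjusted p = 0.3 with an estimated correlation. The thioredoxin H3 gene Niben101Scf00539g07015.1 rose by 0.81 ± 0.22 (adjusted p = 0.019), and had 0.68 to 0.8, adjusted p = 0.054 to 0.059, without mock total 5 or heat total 2, 3 or 4. Peroxiredoxin-2 (Niben101Scf12674g00009.1) fell by 1.39 ± 0.27 (adjusted p = 0.0031). Of 105 genes annotated to histones, 23 rose and 1 fell (28 and 1 adjusted over the list alone). The histone list had adjusted p = 0.00053, and adjusted p = 0.66 with an estimated correlation. That call ended without mock polysome library 3 (adjusted p = 0.073). An H2A.1 gene (Niben101Scf05962g04009.1) rose by 1.43 ± 0.25 (adjusted p = 0.0015). The H2B gene Niben101Scf02182g02007.1 rose by 1.16 ± 0.33 (adjusted p = 0.024), and had 0.96 to 1.16, adjusted p = 0.057 to 0.064, without mock total 7, heat total 2, 3 or 4, mock polysome 4 or heat polysome 5. The member that fell, an enzyme that methylates histones rather than a histone (Niben101Scf02471g06004.1), fell by 0.96 ± 0.31 (adjusted p = 0.04). It had -1.04 to -0.85, adjusted p = 0.056 to 0.095, without mock total 6 or 7, heat total 2, 3 or 4, mock polysome 4 or heat polysome 6 or 7. With mock total libraries 6 and 7 left out, Niben101Scf02182g02007.1 had 0.95, this enzyme had -0.67 and the list had a median of 0.34.

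Of 67 organelle-encoded genes, 16 rose and 2 fell (28 and 2 adjusted over the list alone). The organelle-encoded list had adjusted p = 0.00012, and adjusted p = 0.63 with an estimated correlation. Without mock total libraries 6 and 7 its median moved from 2.63 to -0.45. A mitochondrial NADH dehydrogenase subunit 2 (Niben101Scf00451g00004.1) rose by 4.12 ± 0.95 (adjusted p = 0.0085) on 3 reads above the minimum in mock polysome RNA, and had 1.34 (adjusted p = 0.73) without both libraries. A chloroplast envelope membrane protein (Niben101Scf02836g01002.1) fell by 1.37 ± 0.25 (adjusted p = 0.002). A photosystem II CP43 gene (Niben101Scf00568g04011.1) rose by 3.78 ± 1.05 (adjusted p = 0.021), and had 3.15 to 3.82, adjusted p = 0.052 to 0.064, without mock total 6, heat total 2, 3 or 4, mock polysome 4 or heat polysome 5. Its value was -0.33 without libraries 6 and 7. In the added lists, 41 of 105 plastid type genes rose (adjusted p = 4.8e-11, and adjusted p = 0.35 with an estimated correlation), with adjusted p = 0.57 without both libraries. Of 50 mitochondrial type genes, 18 rose (adjusted p = 2.3e-05, and adjusted p = 0.35 with an estimated correlation), against 1 without both libraries (adjusted p = 0.57). Of 138 nuclear-encoded photosynthesis genes, 59 rose and 2 fell (adjusted p = 4.8e-13, and adjusted p = 0.35 with an estimated correlation), against 35 and 1 without both (adjusted p = 3.8e-15). Of 76 carbon fixation genes, 21 rose and 3 fell (25 and 4 adjusted over the list alone). The carbon fixation list had adjusted p = 0.0037, and adjusted p = 0.46 with an estimated correlation, and counts of 4 and 1 without both libraries (adjusted p = 0.03).

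Of 115 proteasome and ubiquitin genes, 30 rose and 6 fell (39 and 11 adjusted over the list alone). The proteasome list had adjusted p = 0.0039, and adjusted p = 0.46 with an estimated correlation. Of 150 ethylene response factor genes, 9 rose and 4 fell (5 and 1 adjusted over the list alone). The ethylene factor list had adjusted p = 0.0037, and adjusted p = 0.14 with an estimated correlation. Of 396 organellar ribosomal protein genes, 74 rose and 18 fell (77 and 21 adjusted over the list alone). The organellar ribosomal list had adjusted p = 0.016, and adjusted p = 0.66 with an estimated correlation. It had adjusted p = 0.073 to 0.19 without mock total 7 or mock polysome 3. Of 128 auxin response genes, 18 rose and 1 fell (18 and 1 adjusted over the list alone). The auxin list had adjusted p = 0.021, and adjusted p = 0.46 with an estimated correlation. The auxin list had adjusted p = 0.051 to 0.15 without mock polysome 3 or heat polysome 7. Of 51 galactinol and LEA genes, linked to dehydration tolerance, 6 rose and 1 fell (6 and 1 adjusted over the list alone). The galactinol and LEA list had adjusted p = 0.033, and adjusted p = 0.46 with an estimated correlation. It had adjusted p = 0.05 to 0.22 without mock total 5 or 7, heat total 2 or 3, mock polysome 3 or heat polysome 5. Of 8 bridging factor and DREB genes, stress regulators, 2 rose (3 adjusted over the list alone). The bridging factor list had adjusted p = 0.039, and adjusted p = 0.3 with an estimated correlation. It had adjusted p = 0.05 to 0.077 without mock total 6 or 7, heat total 2 or 3, mock polysome 2 or 4 or heat polysome 7. Calls without mock total libraries 6 and 7 together ended for organellar ribosomal proteins (adjusted p = 0.44) and for auxin response, galactinol and LEA, and bridging factor and DREB genes (adjusted p = 0.17 in each).

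Of 9 HSP90 genes, 4 fell (4 adjusted over the list alone). The HSP90 list had adjusted p = 0.0046, and adjusted p = 0.18 with an estimated correlation. In the added HtpG list 8 of 23 fell (adjusted p = 0.0016, and adjusted p = 0.14 with an estimated correlation). The HtpG gene Niben101Scf06890g01022.1 fell by 0.87 ± 0.21 (adjusted p = 0.01). Niben101Scf04847g03018.1 fell by 0.77 ± 0.24 (adjusted p = 0.036), and had -0.79 to -0.69, adjusted p = 0.064 to 0.096, without mock total 5 or 6, heat total 2, 3 or 4 or heat polysome 6 or 7. Niben101Scf06890g01022.1 had -0.77 (adjusted p = 0.11) and Niben101Scf04847g03018.1 had -0.87 (adjusted p = 0.11) without mock total libraries 6 and 7. Niben101Scf00414g06008.1 had 0.38 ± 0.23 (adjusted p = 0.28). Of 40 RNA silencing genes, 1 rose and 8 fell (1 and 9 adjusted over the list alone). The RNA silencing list had adjusted p = 0.0046, and adjusted p = 0.3 with an estimated correlation. Of 184 pre-mRNA splicing genes, 14 rose and 28 fell (15 and 29 adjusted over the list alone). The splicing list had adjusted p = 0.024, and adjusted p = 0.3 with an estimated correlation. Of 54 HSP70 genes, 4 rose and 5 fell (3 and 5 adjusted over the list alone). The HSP70 list had adjusted p = 0.033, and adjusted p = 0.3 with an estimated correlation. The HSP70 list had adjusted p = 0.056 to 0.087 without mock total 5 or heat polysome 5. Of 42 ER protein folding genes, 3 rose and 7 fell (3 and 8 adjusted over the list alone). The ER folding list had adjusted p = 0.033, and adjusted p = 0.46 with an estimated correlation. It had adjusted p = 0.054 to 0.06 without mock total 5, mock polysome 4 or heat polysome 7. With an estimated correlation the lowest adjusted p of any list was 0.081, 4 lists had an unadjusted p under 0.05, and fry called 13.

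The other 13 planned lists had adjusted p of 0.086 to 0.86 in efficiency. Among them, cytosolic ribosomal proteins and defence genes had medians (0.06 and 0.11) and means (0.04 and 0.01) above 0 while the test pointed down. Some were called with libraries left out. These were heat shock transcription factors (adjusted p = 0.031 without mock total 7 and 0.013 without 6 and 7), cytosolic ribosomal proteins (adjusted p = 0.046 without mock total 7) and wound and jasmonate genes (adjusted p = 0.023 without mock polysome 4). The others were cell wall genes (adjusted p = 0.0064 without mock polysome 2), vascular tissue (adjusted p = 0.01 to 0.017 without mock total 7 or mock polysome 3 and 0.013 without 6 and 7) and epidermis and cuticle (adjusted p = 0.026 without mock polysome 2).

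Efficiency changes went with the length of the homolog that the annotation names, which 8369 genes (24.4%) carry. With homologs of up to 250, up to 500, up to 1000 and over 1000 residues, the median log2 efficiency change was 0.34, 0.2, -0.17 and -0.65. Spearman's correlation across these genes was -0.32, and a check of length over all genes is void, since under 80% have a value. Title numbers of the libraries that raise (5 to 7) and lower (2 to 4) the efficiency contrast form separate sets, so the contrast cannot be told apart from a difference between them. The same holds for polysome against total RNA in each treatment, and only the mean heat effect is balanced. In heat against mock, a set difference common to total and polysome RNA would turn their changes opposite. The Pearson correlation of 0.819 argues against it as main source over all genes. Calls fell by over 1.5 times without heat total library 2, 3 or 4 (4234, 4150 and 4166 genes) and without mock total 6 and 7.

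Polysome RNA was also compared with total RNA within each treatment, to show which transcripts were over- or under-represented on ribosomes. In mock plants, a non-specific lipid-transfer protein 1 (Niben101Scf29144g00011.1), a small secreted protein, had 914 ± 164 CPM in total and 11500 ± 4740 in polysome RNA. Ribosomal protein, histone and light reaction genes were enriched in 226 of 388, 65 of 105 and 115 of 250 genes. Splicing and RNA silencing genes were depleted in 96 of 184 and 22 of 40. With an estimated correlation these lists had adjusted p = 0.13 to 0.47.

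In mock plants 9275 genes were higher and 9327 lower in polysome RNA. With RLE size factors 10012 were higher and 8682 lower, and more were higher also with DESeq2 (9748 and 8279), a mean of at least 5 CPM (6177 and 6119), or without mock total 7 (9032 and 8947) or mock polysome 3 (9295 and 9154). The 4 largest enrichments began with the lipid-transfer protein, at 3.65 ± 0.28 (adjusted p = 8.7e-08), and a thionin-like gene (Niben101Scf09801g02012.1), of a family of small defence peptides, at 3.58 ± 0.55 (adjusted p = 5.3e-05). A photosystem II 5 kDa protein (Niben101Scf00290g00017.1) followed at 3.45 ± 0.19 (adjusted p = 1.3e-08), and a gene named only by a Brassica homolog (Niben101Scf01033g04010.1) at 3.36 ± 0.33 (adjusted p = 7.8e-07). The 4 largest depletions were in a vacuolar sorting protein 18 gene (Niben101Scf02077g12027.1), at -5.95 ± 0.3 (adjusted p = 7.1e-09), GTPase Der (Niben101Scf39490g00008.1), at -5.55 ± 0.28 (adjusted p = 7.1e-09), and the Clp subunit ClpA (Niben101Scf00213g02005.1), at -5.04 ± 0.28 (adjusted p = 1.6e-08). Ferredoxin-dependent glutamate synthase (Niben101Scf12966g00016.1), an enzyme of ammonium assimilation, lay at -4.98 ± 0.22 (adjusted p = 2.6e-09). Of 388 cytosolic ribosomal protein genes, 226 were higher and 37 lower (229 and 38 adjusted over the list alone). The cytosolic ribosomal list had adjusted p = 1.5e-08, and adjusted p = 0.47 with an estimated correlation. Of 128 auxin response genes, 78 were higher and 8 lower (79 and 8 adjusted over the list alone). The auxin list had adjusted p = 4.1e-08, and adjusted p = 0.19 with an estimated correlation. Of 279 antioxidant enzyme genes, 146 were higher and 34 lower (148 and 35 adjusted over the list alone). The antioxidant list had adjusted p = 5.3e-06, and adjusted p = 0.19 with an estimated correlation. Of 184 pre-mRNA splicing genes, 25 were higher and 96 lower. The splicing list had adjusted p = 3.6e-06, and adjusted p = 0.13 with an estimated correlation. Of 67 organelle-encoded genes, 2 were higher and 41 lower (2 and 46 adjusted over the list alone). The organelle-encoded list had adjusted p = 0.0085, and adjusted p = 0.64 with an estimated correlation. Without mock total libraries 6 and 7, 14 of these were higher and 1 lower. The test called 12 lists up and 6 down. With an estimated correlation 0 of the 30 lists passed camera (6 at an unadjusted p under 0.05), and fry called 26. HSP70 chaperones (median 0.13, mean -0.14) and carbon fixation (0.14 and -0.22) differed in sign between median and mean.

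In heated plants, light reaction genes were enriched in polysome RNA in 150 of 250 genes (median 1.48, adjusted p = 0.16 with an estimated correlation). The median in mock plants was 0.38, and 1.01 without mock total libraries 6 and 7. Small heat shock proteins were enriched in 59 of 81 genes (median 1.42). Splicing genes were depleted in 113 of 184 and HSP90 genes in 8 of 9. Differences between the treatments were tested as the efficiency changes.

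In heated plants 10560 genes were higher and 9743 lower in polysome RNA (10659 and 11161 with the 6 libraries alone). The 4 largest enrichments were in an MLO-like protein 4 gene (Niben101Scf01993g08022.1), at 3.96 ± 0.41 (adjusted p = 8.6e-07), the transcription factor RADIALIS (Niben101Scf08718g00004.1), at 3.36 ± 0.29 (adjusted p = 1.3e-07), and a calcium-dependent protein kinase 29 (Niben101Scf00508g00002.1), at 3.28 ± 0.3 (adjusted p = 2.6e-07). A thionin-like gene (Niben101Scf05375g00004.1) lay at 3.24 ± 0.64 (adjusted p = 0.00041). On the depleted side, sacsin (Niben101Scf04567g03028.1) had a ratio of 114 (95% counting interval 38.7 to 553) of total to polysome RNA (adjusted p = 4.9e-08). A leucine-rich repeat protein 1 (Niben101Scf01586g01010.1) lay at -5.73 ± 0.36 (adjusted p = 1.5e-08), a regulator of nonsense transcripts 1 homolog (Niben101Scf14542g00033.1), a helicase of RNA quality control, at -5.3 ± 0.32 (adjusted p = 1.1e-08), and an embryo defective gene (Niben101Scf06424g02028.1) at -5.29 ± 0.34 (adjusted p = 1.5e-08). The test called 17 lists up and 7 down, of which 6 held with an estimated correlation. Of 81 small heat shock protein genes, 59 were higher and 1 lower (59 and 1 adjusted over the list alone). The small heat shock protein list had adjusted p = 6.1e-10, and adjusted p = 0.034 with an estimated correlation. Of 279 antioxidant enzyme genes, 177 were higher and 17 lower (180 and 17 adjusted over the list alone). The antioxidant list had adjusted p = 1.2e-10, and adjusted p = 0.034 with an estimated correlation. Of 150 ethylene response factor genes, 71 were higher and 18 lower (71 and 18 adjusted over the list alone). The ethylene factor list had adjusted p = 0.00046, and adjusted p = 0.034 with an estimated correlation. Of 184 pre-mRNA splicing genes, 20 were higher and 113 lower (21 and 117 adjusted over the list alone). The splicing list had adjusted p = 3.9e-09, and adjusted p = 0.034 with an estimated correlation. Of 40 RNA silencing genes, 1 was higher and 29 lower (1 and 30 adjusted over the list alone). The RNA silencing list had adjusted p = 1.4e-06, and adjusted p = 0.034 with an estimated correlation. Of 9 HSP90 genes, 8 were lower (8 adjusted over the list alone). The HSP90 list had adjusted p = 0.00032, and adjusted p = 0.034 with an estimated correlation. Of 250 light reaction genes, 150 were higher and 8 lower (151 and 8 adjusted over the list alone). The light reaction list had adjusted p = 2.1e-15, and adjusted p = 0.16 with an estimated correlation.

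Median changes fell with homolog length in both treatments. They went from 0.71 at up to 250 residues to -0.7 at over 1000 in mock plants and from 1.09 to -1.39 in heated plants, with Spearman correlations of -0.372 and -0.555 across the 8369 genes.

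**Figure D5:**
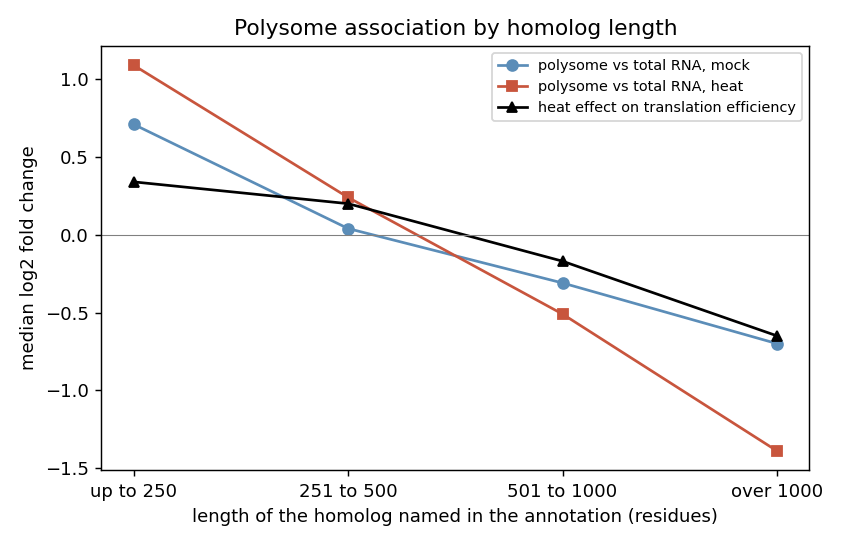
Median log2 fold change (vertical) by length of the homolog named in the annotation, in residues (horizontal, 4 classes of 1621, 3580, 2614 and 554 genes), for polysome against total RNA in mock plants (circles), in heated plants (squares) and for the efficiency change (triangles). In heated plants the median goes from 1.09 in the shortest class to -1.39 in the longest.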

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

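Of the tests in this part, those of library 5 against heat, of depth, of shared noise and of the slope, with its 95% interval as the limit, were chosen after the results were seen, as was leaving out libraries 6 and 7. The heat effects in polysome RNA and total RNA differed by the interaction term itself in 3502 genes upward, 2891 genes downward and 12 plus 5 lists (17 lists). With an estimated correlation 0 lists passed camera (4 at an unadjusted p under 0.05, 13 by fry), and organelle-encoded genes turned down without mock total libraries 6 and 7 (adjusted p = 0.17). Median log2 efficiency changes of these lists were 0.98 for small heat shock proteins, -0.15 for HSP70 chaperones, -0.66 for HSP90 chaperones, 0.31 for organellar ribosomal proteins, 0.94 for photosynthetic light reactions, 0.49 for carbon fixation, 0.36 for proteasome and ubiquitin, 0.41 for antioxidant enzymes, -0.3 for ER protein folding, 0.52 for galactinol and LEA proteins, 0.44 for multiprotein bridging factor and DREB, -0.52 for RNA silencing, -0.16 for pre-mRNA splicing, 0.48 for ethylene response factors, 0.46 for auxin response genes, 0.57 for histones and 2.63 for organelle-encoded genes. Named genes with a rise in efficiency, with the log2 change, were Niben101Scf25930g00016.1 (5.03), Niben101Scf07103g01021.1 (4.81), Niben101Scf11178g01008.1 (4.64), Niben101Scf00173g09004.1 (4.56), Niben101Scf03068g00011.1 (4.52), Niben101Scf02160g06002.1 (4.5), Niben101Scf39490g00008.1 (4.42), Niben101Scf03236g02005.1 (4.37), Niben101Scf09262g01017.1 (1.51), Niben101Scf10384g00014.1 (1.34), Niben101Scf05621g13007.1 (2.66), Niben101Ctg10591g00003.1 (2.73), Niben101Scf00539g07015.1 (0.81), Niben101Scf05962g04009.1 (1.43), Niben101Scf02182g02007.1 (1.16), Niben101Scf00451g00004.1 (4.12) and Niben101Scf00568g04011.1 (3.78). Those with a fall were Niben101Scf07488g00024.1 (-3.45), Niben101Scf03550g00021.1 (-3.22), Niben101Scf00327g00011.1 (-3.22), Niben101Scf01395g05008.1 (-3.2), Niben101Scf01869g00012.1 (-3.06), Niben101Scf03809g00009.1 (-3.01), Niben101Scf03861g02041.1 (-2.96), Niben101Scf02072g02027.1 (-2.96), Niben101Scf04018g06007.1 (-0.86), Niben101Scf12674g00009.1 (-1.39), Niben101Scf02471g06004.1 (-0.96), Niben101Scf02836g01002.1 (-1.37), Niben101Scf06890g01022.1 (-0.87) and Niben101Scf04847g03018.1 (-0.77).

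Transcripts of plastid genome type summed to 9947 and 9872 CPM in mock total libraries 6 and 7 and to 571.6 in library 5. Deeper sequencing is argued against, since libraries 6 and 7 held at most 1.06 times the counts of library 5. If organellar RNA without poly(A) tails had entered these libraries, mitochondrial transcripts would be higher there too, and they were, by a median log2 of 2.68 (95% interval 2.19 to 3.1, 50 genes), against 3.76 for the plastid type and -0.01 for all genes, so this is a candidate explanation. A fall of plastid transcripts with heat stays open: mock library 5 lay 0.7 (0.52 to 0.82) above the heat total mean in median log2, but a single mock library cannot decide it. In polysome RNA the sums were 959.4, 2530 and 689.2 CPM in mock libraries 2, 3 and 4, where library 3 stood apart, against 916.7, 517.8 and 567.2 in heat, with a median log2 change of -1.14 (adjusted p = 0.052).

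Genes that rose in total RNA were called down in efficiency 1422 times and up 797 times, against 744 and 901 for independent lists, and genes that fell 298 and 1266 times (819 and 992). The covariance of the total RNA and efficiency changes was -0.28 against -0.154 in counts simulated with no efficiency change, a difference of -0.126. Their Pearson correlation was -0.209 against -0.22 simulated and shows no excess, and part of the excess in calls over independent lists may come from the shared libraries. Noise of shared libraries as the whole cause is argued against by covariances of -0.135 to -0.08 taken from different libraries (-0.148 from the same ones, highest -0.08), and libraries 6 and 7 by 588 falls and 355 rises without them, a ratio of 1.66. The trend on homolog length was removed in the 4606 of 18448 genes that have one. Among these genes the highest covariance from different libraries moved from -0.084 to -0.028 (lowest -0.101). With so few genes covered this check is void, and length stays open. A lag of polysome loading over the whole transcriptome needs a slope below 1, and the slope of 1.077 (95% interval 0.97 to 1.18) leaves it open, as it leaves a difference between the sets of title numbers, which cannot be told apart from efficiency.

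Small heat shock proteins had a median log2 efficiency change of 0.98, against 0.07 for all genes. The count floor is argued against by a median of 0.8 in the 43 members averaging at least 10 counts in both mock groups. Its 95% interval over genes, 0.3 to 0.99, leaves out spread between libraries. The 10 members with a text of their own had 0.98 (0.31 to 1.31), but genes with other texts can share reads. Short transcripts gained in heated polysome libraries stay a candidate explanation for part of it: 1479 genes outside the list with homologs of 100 to 250 residues, of the 24.4% of genes with a homolog length, had a median of 0.37 (0.32 to 0.42), above 0.3, the lower end of the interval of the 43 members. Shared reads, a change in translation and the sets of title numbers stay open as well.

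Other groupings of the same samples were counted. Among 30 drawn splits of 12 libraries, the real one gave 6393 efficiency calls and was 1 of 30 with as many. All others gave 0 in edgeR at the adjusted threshold. The highest gave 12537 genes at an unadjusted p under 0.05, against 11016 for the real one. With every other split at that floor the adjusted count does not exclude chance, which stays open, and what that other split separates was not tested. For the mean heat effect, 22559 calls against at most 6172 (1 of 30, the lowest share possible) argue against chance. Of the 17 lists called in efficiency, 9 of 30 splits called as many (highest other 20). Other splits mix groups and can keep real effects, so list shares are no chance rates and leave chance open. The comparisons of 3 with 3 libraries make only 10 splits, too few for a share under 0.05. Fitted on those libraries alone, the real and the highest other counts were 20159 and 0 genes in total RNA, 16186 and 0 in polysome RNA, 15591 and 0 for polysome against total RNA in mock and 21820 and 0 in heat by edgeR. At an unadjusted p under 0.05 the highest others were 342, 340, 1668 and 128. For lists they were 19 and 17 in total RNA (1 of 10 splits as large) and 14 and 18 in polysome RNA (6 of 10).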

How the results depend on the processing

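Fits without mock total libraries 6 and 7 and with counts less 1, and refits of the lists and of the correlation with another scaling or a library left out, were chosen after seeing the data. RLE size factors moved the median of all genes by 0.071 in total RNA, 0.017 in polysome RNA and -0.054 in efficiency. RLE, no filter, counts less 1, DESeq2, limma-voom and fits of the compared libraries alone kept each count of genes within 1.5 times. With a mean of at least 5 CPM, which tests fewer genes, 11757 genes were called in total RNA, 12246 in polysome RNA, 12296 for polysome against total RNA in mock and 13528 for the mean effect. An absolute log2 fold change over 1, a stricter limit, left 11973, 11689 and 12378 in total RNA, in mock and for the mean. Without libraries 6 and 7, 2434 genes were called in efficiency and 12759 in total RNA, and fewer samples lower such counts. With 1 library left out, calls were 16171 to 20057 in total RNA, 17293 to 19719 in polysome RNA, 4150 to 7498 in efficiency (lowest without heat total 3), 16095 to 19110 and 18111 to 21152 for polysome against total RNA in mock and heat, and 21685 to 22899 for the mean effect.

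Lists called numbered 17 to 19, 12 to 14 and 14 to 18 in total RNA, polysome RNA and efficiency with 1 library left out. With an estimated correlation they numbered 2, 2 and 0 in camera (9, 7 and 4 at an unadjusted p under 0.05, and 23, 20 and 13 by fry). Of 90 list results, RLE left 89 on the same side of the threshold and made 1 pass (wound and jasmonate genes in total RNA), and fry left 65, with 8 lost, 14 gained and 3 turned. These directions turned, with the adjusted p there. Bridging factor and DREB genes in total RNA pointed up by fry (1e-05) and without libraries 6 and 7 (0.84). In polysome RNA, cell wall (0.94) and vascular genes (1) turned up without mock polysome 2 and epidermis genes down without mock polysome 3 (0.73), against 0.18 for vascular genes without mock polysome 3 and 0.43 for epidermis genes without mock polysome 2. In efficiency, chaperonins turned down without libraries 6 and 7 (0.93), mock total 7 (0.99), mock polysome 2 (0.95) or heat polysome 6 (0.93), and had at lowest 0.72, upward, without heat polysome 5. Cytosolic ribosomal proteins turned up by fry (0.91) and without mock total 5 (0.63), mock total 6 (0.52) or mock polysome 2 (0.19), and pointed down with 0.046 without mock total 7 and 0.96 without heat total 2. Defence genes turned up by fry (0.91), without libraries 6 and 7 (0.73) and without mock total 7 (0.97), with 0.43 downward without mock total 5. Cell wall genes turned down without mock polysome 3 (0.78), with 0.0064 upward without mock polysome 2. Clock genes turned up without libraries 6 and 7 (0.77), mock total 7 (0.99) or mock polysome 3 (0.97), with 0.28 downward without mock polysome 2, and organelle-encoded genes down without libraries 6 and 7 (0.17). The cause was not tested.

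Named genes kept direction and call in 114 of 114 results with RLE, 112 of 112 with DESeq2 and 1319 of 1368 with a library left out. In efficiency, 9 of 31 called genes lost the call with a library left out and 15 without libraries 6 and 7. The efficiency change of Niben101Scf01116g01004.1 turned to 0.01 without mock total 7 (-0.32 without mock polysome 2) and to 0.07 without libraries 6 and 7, where that of Niben101Scf00568g04011.1 turned to -0.33, and the cause was not tested. With members at their bounds, the polysome RNA medians of HSP100 and Clp genes and of defence genes moved from 0.4 to 0.34 and from 0.12 to 0.13. The correlation of polysome and total RNA changes was 0.884 (Pearson) and 0.861 (Spearman) with a slope of 0.986 among genes called in total RNA, and 0.868 (Pearson) among genes above the median level. With a library left out it was 0.78 to 0.82 (Pearson), 0.692 to 0.742 (Spearman) and 1.026 to 1.101 (slope), and lowest without mock polysome 2 for both correlations.

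With the title number as a block, the mean heat effect called 21829 genes (10453 up and 11376 down). Same-number libraries correlated at -0.07 to 0.008 in their deviations from group means. Such pairs differ in treatment and fraction, so pairing stays open. No other comparison could be paired, as its groups share no number or, for efficiency, the number sets equal the contrast. Alternatives with a pseudocount, planned for normalized values, were not run, since counts were tested.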

Other observations

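GO terms of the deposited annotation, tested with camera after the data were seen, covered groups beyond the lists and some that overlap them, such as light harvesting. Of 405 terms, 32 were called up and 32 down in total RNA, 26 and 14 in polysome RNA and 56 and 55 in efficiency. In total RNA, 16 of 23 genes of Ran GTPase binding, a term of transport through the nuclear pore, rose (median 0.91, adjusted p = 9e-05, and adjusted p = 0.15 with an estimated correlation). Of 39 genes of the response to hormone, 29 fell and 1 rose (median -1.06, adjusted p = 1.1e-05, and adjusted p = 0.14 with an estimated correlation). In polysome RNA, 54 of 84 nucleocytoplasmic transport genes rose and 11 fell (median 0.65, adjusted p = 0.00055, and adjusted p = 0.62 with an estimated correlation).

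In efficiency, light harvesting genes rose in 40 of 71 (median 0.87, adjusted p = 8.1e-12, and adjusted p = 0.54 with an estimated correlation). Genes of glucan synthases, enzymes that make callose, fell in 11 of 20 (median -1.18, adjusted p = 3.8e-07, and adjusted p = 0.38 with an estimated correlation). In heated plants, 55 of 79 aminoacyl-tRNA ligase genes, which load tRNAs with amino acids, were lower and 3 higher in polysome than in total RNA (median -0.98, adjusted p = 9.9e-09, and adjusted p = 0.15 with an estimated correlation). No hypothesis on them was tested.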
